A study of Canis lupus familiaris with 11 samples.

How the data were processed

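RNA was measured in 11 samples of MDCKII dog kidney epithelial cells in 4 groups, wild-type control (3 libraries), wild-type compressed (3), LMNA KO control (2) and LMNA KO compressed (3). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells grew for 3 to 4 d to a confluent sheet and were collected directly or after lateral compression and 2 h of recovery, and polyadenylated RNA was captured with oligo(dT) and copied to cDNA from random hexamers. How the compression was applied is not given in the sources used here, nor is whether the kit marks strand. Reads of overlapping or antisense genes can therefore not be told apart.

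Per the submitters' processing notes, the tools were CASAVA, FastQC and HISAT2 version 2.0.5 and the genome build was CanFam3.1; the gene counter, the annotation release and any filter are not given in the sources used here. The authors deposited whole-number counts per gene, with no normalization, in a table of 26178 genes, and 0 rows of it named no gene. The deposited FPKM values are these counts per kilobase of the authors' gene length and per 1e6 of an effective library size, which was 0.964 to 1.049 times the count total. The FPKM table was used as an alternative only. Totals ran from 10420214 to 17999623 counts per library. This depth leaves genes under about 1 CPM with few reads, and intervals and floors given for low counts cover counting error only. No 2 replicates of a group held the same values or agreed within sampling noise, the lowest chi-square per gene between replicates being 5.99.

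Gene symbols came from the table itself, 14932 from its gene name column and 2414 from the UniProt match in its description column, which is less certain; 8832 genes had no symbol, among them 1598 that the authors assembled. Where both sources named a protein-coding gene, 90.5% gave the same symbol. Of 1222 entries in 36 gene lists, 95.8% were found. The last 3 of the lists hold markers of fibroblasts and smooth muscle, endothelium and immune cells. The reference genome was not used here, so GC content was not analysed.

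Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups (13560 genes), libraries were scaled by TMM, and one quasi-likelihood fit of 4 groups over all 11 libraries left 7 residual degrees of freedom. Contrasts gave compression in each genotype, the difference between KO and wild-type cells with and without compression, and the interaction of genotype and compression. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM with a mean and SD are TMM-scaled. A fold against a group at 0 reads is a lower bound set by a floor of 3 counts over the group. Gene lists with at least 5 measured members (33 lists) were tested in the same fit with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over lists. Camera with an estimated correlation and fry were run beside it. Members past 0.05 were counted over all genes tested and adjusted over the list alone.

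The genes named follow a rule set with the comparisons, lists and main alternatives. It takes LMNA in each comparison, and the 6 largest increases and 6 largest decreases among called genes with a symbol, a mean of at least 2 CPM in the higher group and no overlap between the libraries of the groups. It adds, for each list called by camera, up to 3 called members with the smallest p in the direction of the list, and, for a list described but not called, up to 3 members with the smallest p. For called lists with no member past the threshold, up to 2 members with the smallest p are given as values, which is an extension made after the data were seen. PTGS2, SLC6A12 and SCAMP5 fall under the rule, and giving them by library was chosen after their values were seen. Not every gene that the rule takes is named in the text. The markers of other cell types and the library-level measures were chosen outside this rule.

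The alternatives were DESeq2 1.42.0, RLE scaling, library size alone, no filter, a stricter filter of 1 CPM in 3 libraries, a robust fit, a minimum log2 fold change of 1, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) over genes with an FPKM of at least 1 in at least 2 libraries, a fit of the 2 groups alone, a term for the replicate number, and leaving out each library in turn. Added after the data were seen were fits without 3 or 2 libraries that stood apart, a loess correction of each library for local gene density within 1 Mb, and the nuclear envelope list without LMNA. Values that compare single measures between libraries were tested by exact rearrangement of libraries within each genotype, chosen after the results were seen. The rearrangements assume that compression has no effect in either genotype. For a difference between the genotypes they are therefore not an exact test of equal effects.

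The scripts' tests were checked on counts simulated from these libraries with 200 genes changed by known folds per comparison. For compression in wild-type cells 48.5% of genes changed by 2-fold and 94% of those changed by 4-fold were recovered. The figures for KO cells were 24% and 92.5%, and for the interaction 0% and 73%. For KO against wild-type cells they were 35% and 89.5% without compression and 43.5% and 95.5% after it. Figures were drawn with matplotlib 3.10.9.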

Results

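Gene expression was measured by RNA sequencing in MDCKII cells, a dog kidney epithelial line that forms a tight, polarised sheet in culture. The series title asks how an epithelium answers to being compressed sideways and what part lamin A plays. Lamin A and lamin C, both encoded by LMNA, are filament proteins that line the inner face of the nuclear envelope. Wild-type (WT) cells and LMNA knockout (KO) cells were grown for 3 to 4 d, until the sheet was confluent. They were then collected as controls, or compressed laterally and collected after 2 h of recovery. These conditions follow the sample labels, while the design text of the series describes other time points and wild-type cells only. The labels name no sham handling and no recovery period for the controls. A difference between compressed and control cells can therefore not be told apart from an effect of handling or of the recovery time. The 11 libraries comprised 3 WT control, 3 WT compressed, 2 KO control and 3 KO compressed samples. The libraries held 10420214 to 17999623 counts each. The labels do not say that replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

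LMNA RNA was low in every library labelled KO and high in every library labelled WT. The gene lies on chromosome 7, from 41699201 to 41719658 on the minus strand of CanFam3.1. In WT control cells LMNA stood at 677.6, 1250.1 and 961.5 counts per 1e6 counts of the library (CPM), and in WT compressed cells at 839.1, 844.5 and 713.9 CPM. In KO control cells it stood at 39.7 and 53 CPM, and in KO compressed cells at 34.4, 24.5 and 43.0 CPM. The KO libraries still held 291 to 954 LMNA reads each. The KO to WT log2 fold change was -4.38 ± 0.30 (SE) without compression and -4.53 ± 0.25 after it, with adjusted p-values of 1.57e-05 and 1.19e-06 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Both calls held without each library of the groups compared in turn. Between compressed and control cells LMNA differed by -0.22 ± 0.22 in WT cells and by -0.37 ± 0.25 in KO cells, with edgeR adjusted p-values of 0.5 and 0.773, so neither passed the test.

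**Figure D1:**
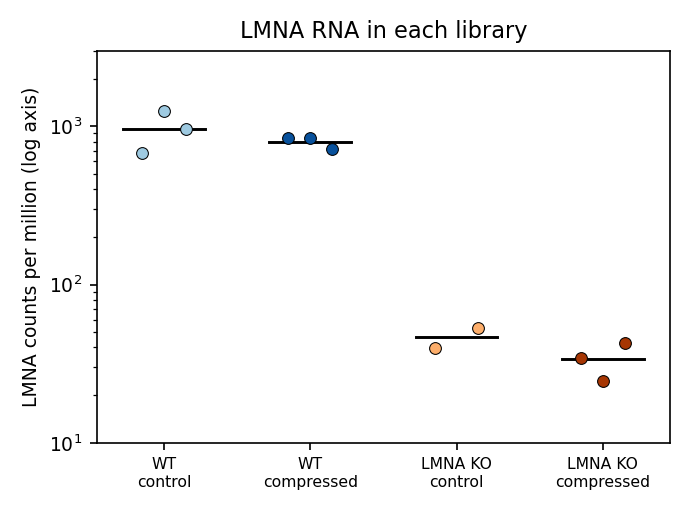
LMNA CPM on a log axis in each of the 11 libraries (points), by genotype and treatment, with group means as bars. The 5 KO libraries lie between 24.5 and 53 CPM, below the 6 WT libraries at 677.6 to 1250.1 CPM.

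In WT cells after compression and 2 h of recovery, the RNA of immediate early genes was lower than in controls. These are the fast transcription factors and phosphatases that growth signals switch on. The RNA of interferon-stimulated genes, the antiviral set, was higher, both by limma camera at a preset correlation between genes. Neither list passed with a correlation estimated from the data, where the adjusted p by camera was 0.106 for immediate early genes and 0.41 for interferon-stimulated genes. FOS, a subunit of the AP-1 transcription factor, fell from 80.6 ± 17.4 to 35.2 ± 4.32 CPM (SD, n = 3 per group), and the transcription factor CSRNP1 fell from 54.9 ± 3.44 to 19.9 ± 4.21 CPM. SAMD9L, an antiviral factor, rose from 193 ± 7.98 to 416 ± 36.7 CPM, and RSAD2, the antiviral enzyme viperin, rose from 15.2 ± 16.5 to 136 ± 63.5 CPM. The laminin chain LAMB3 of the basement membrane fell, while the kinetochore gene NDC80 and the spindle motor KIF11 rose.

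Of 13560 genes tested, 848 passed an adjusted p of 0.05 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 522 higher and 326 lower after compression. Their adjusted p-values lay between 0.041 and 0.0499, so all of them were close to the threshold. At an unadjusted p under 0.05 there were 4307 genes, where 678 would be expected by chance. Among the called genes 307 changed by at least 1 on the log2 scale. The count was 1379 without WT control replicate 1, 1 without WT control replicate 2, 1 without WT control replicate 3, 0 without WT compressed replicate 1, 0 without WT compressed replicate 2 and 1 without WT compressed replicate 3, and in the 2 fits that called 0 genes edgeR still gave 3274 and 4245 genes at an unadjusted p under 0.05. It was also 0 in edgeR without KO control replicate 1 (3897 at an unadjusted p under 0.05) or KO control replicate 2 (3899), and 3066 without KO compressed replicate 2. None of the 45 calls that the rule for named genes takes in this comparison was kept without each of its 6 libraries in turn. With all libraries DESeq2 called 2476 genes and limma on log2(FPKM + 1) called 0 with 4160 at an unadjusted p under 0.05. With a term for the replicate number edgeR called 0 genes, and 3439 had an unadjusted p under 0.05.

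The largest increases among named genes with no overlap between groups were led by interferon-stimulated genes. RSAD2 changed by 3.15 ± 0.72 on the log2 scale (SE), DDX60 by 2.48 ± 0.60, IFI44L by 2.12 ± 0.45 and RTP4 by 1.75 ± 0.49. ERICH2, named through a protein match, changed by 1.77 ± 0.45, and TXN, the redox protein thioredoxin, by 1.63 ± 0.38. The largest decreases were in SLC6A12, a betaine and GABA transporter, at -7.05 ± 1.85, in a locus on an unplaced scaffold matched to ADI1 at -4.23 ± 0.87 and in C6orf15 at -4.06 ± 1.07. NR4A1, an immediate early nuclear receptor, fell by 2.89 ± 0.55, the cytokine CSF2 by 2.75 ± 0.71 and the secretory membrane protein SCAMP5 by 2.73 ± 0.70. WT control replicate 1 set much of the size for SLC6A12, with 91.5 CPM against 1.48 and 1.22 CPM in the other control libraries, and for SCAMP5, with 322 CPM against 43.8 and 63.0 CPM. Without that library SLC6A12 changed by -2.54 and SCAMP5 by -1.31 and neither passed the test.

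Gene lists fixed before the data were examined were tested with limma camera at a preset correlation between genes, and 15 of 33 were called in WT cells, 5 higher and 10 lower. With a correlation estimated for each list, 0 of the 15 passed, the smallest adjusted p being 0.106. Other groupings of the 6 WT libraries into 3 and 3 also called lists, between 1 and 16 of them, so a camera call alone does not set compression apart from other groupings of these libraries. By fry, which asks whether members move one way on balance, 3 lists passed: immediate early genes, EGF receptor feedback, and YAP and TEAD targets, each with an adjusted p of 0.00332.

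Immediate early genes had a median log2 fold change of -0.70 over 37 measured members, and 35 of the 37 had negative values. Over all genes tested 7 fell and 0 rose, and adjusted over the list alone 18 fell. The smallest p-values were those of CSRNP1 at -1.46 ± 0.20, FOS at -1.20 ± 0.18 and NR4A1. The camera adjusted p was 2.15e-08, and the adjusted p was 0.106 with an estimated correlation. EGF receptor ligands and feedback genes had a median of -0.47 over 24 members, of which 4 fell over all genes tested and 5 fell adjusted over the list alone. PHLDA1 changed by -1.73 ± 0.34, the stress response gene IER3 by -2.16 ± 0.50 and SPRY2, a feedback inhibitor of receptor tyrosine kinases, by -0.91 ± 0.22. Camera gave an adjusted p of 0.000667, and the adjusted p was 0.106 with an estimated correlation.

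Interferon-stimulated genes had a median of 0.89 over 34 members, with 9 higher over all genes tested and 17 higher adjusted over the list alone. SAMD9L changed by 1.11 ± 0.22, IFIH1, a sensor of double-stranded RNA, by 1.03 ± 0.21 and DTX3L, a ubiquitin ligase, by 1.45 ± 0.30. Camera gave an adjusted p of 2.15e-08, and the adjusted p was 0.41 with an estimated correlation. WT control replicate 1 had the lowest mean score of this list among the 11 libraries, -1.01 on the log2 scale against -0.23 and -0.62 in the other WT controls. NF-kB and inflammatory genes had a median of -0.77 over 20 members. Of these, 3 fell over all genes tested, while 8 fell and 1 rose adjusted over the list alone. LIF changed by -1.91 ± 0.34, CSF2 by the value above, and PTGS2, which encodes cyclooxygenase-2, by -2.49 ± 0.61. PTGS2 stood at 4620 CPM in WT control replicate 1 against 477 and 1090 CPM in the other WT controls, and without that library it had a value of -1.09 and did not pass the edgeR test. The camera adjusted p of the list was 0.00538, and the adjusted p was 0.41 with an estimated correlation.

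Extracellular matrix and remodelling genes had a median of -0.65 over 33 members, with 3 lower over all genes tested and 10 lower adjusted over the list alone. LAMB3 changed by -1.03 ± 0.27 and LOXL2, a collagen crosslinking enzyme, by -1.15 ± 0.32, or -0.74 without WT control replicate 1. Camera gave an adjusted p of 0.000219, and the adjusted p was 0.41 with an estimated correlation. Mitosis genes had a median of 0.37 over 41 members. Over all genes tested 6 rose, and adjusted over the list alone 17 rose and 3 fell. NDC80 changed by 1.13 ± 0.24, SPC25 by 0.79 ± 0.18 and KIF11 by 0.89 ± 0.21. The camera adjusted p was 0.00021, and the adjusted p was 0.41 with an estimated correlation. Primary cilium genes had a median of 0.42 over 39 members, with 4 higher over all genes tested. Adjusted over the list alone, 16 rose and 1 fell. IFT88, which carries cargo along the cilium, changed by 1.02 ± 0.25 and TTC21B by 0.92 ± 0.24. Camera gave an adjusted p of 0.00028, and the adjusted p was 0.41 with an estimated correlation.

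Cytosolic ribosomal protein genes had a median of 0.27 over 63 members, with 5 higher over all genes tested and 8 higher adjusted over the list alone, among them RPL39 at 0.97 ± 0.23, RPS3A at 0.54 ± 0.14 and RPS15A at 0.74 ± 0.19. Camera gave an adjusted p of 0.000375, which was 0.0911 without WT control replicate 1, and the adjusted p was 0.635 with an estimated correlation. Cholesterol synthesis and uptake genes had a median of -0.30 over 29 members, with 5 lower over all genes tested and 6 lower adjusted over the list alone. MVD, an enzyme of sterol synthesis, changed by -0.87 ± 0.24. The camera adjusted p was 0.0175, it was 0.615 without WT control replicate 1, and the adjusted p was 0.635 with an estimated correlation. Nuclear-encoded respiratory chain genes had a median of 0.14 over 57 members. Only NDUFS1 rose over all genes tested, by 0.52 ± 0.13, and 0 rose adjusted over the list alone by edgeR. Camera's adjusted p of 0.0316 became 0.653 without WT control replicate 1 and 0.241 without WT compressed replicate 3, and the adjusted p was 0.747 with an estimated correlation. The 13 mitochondrially encoded genes had a median of -0.32. None of them passed over all genes tested by edgeR, and 4 fell adjusted over the list alone. MT-CO1 had a value of -0.74 ± 0.22 and COX3 one of -0.59 ± 0.17, with edgeR adjusted p-values of 0.0546 and 0.0549. By camera the list had an adjusted p of 0.0286, which became 0.52 without WT control replicate 1 and 0.114 without WT compressed replicate 2, and the adjusted p was 0.635 with an estimated correlation.

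Camera called targets of 4 further signalling pathways lower, each only at the preset correlation. TGF-beta and SMAD targets had a median of -0.46 over 24 members, with 2 lower over all genes tested and 6 lower adjusted over the list alone, including the BMP antagonist NOG at -1.77 ± 0.45 and CTGF at -1.49 ± 0.40, or -0.77 without WT control replicate 1. Tested with camera, the list had an adjusted p of 0.0158, which was 0.0923 without WT control replicate 1, and the adjusted p was 0.41 with an estimated correlation. p53 targets had a median of -0.49 over 22 members, with PLK2 alone lower over all genes tested at -1.61 ± 0.43, or -0.80 without WT control replicate 1, and 3 lower adjusted over the list alone. For this list camera's adjusted p of 0.0286 became 0.414 without WT control replicate 1, and the adjusted p was 0.41 with an estimated correlation. Notch pathway genes had a median of -0.56 over 10 members, with the ligand JAG2 at -1.35 ± 0.33 and the receptor NOTCH1 at -1.66 ± 0.43, or -1.09 without WT control replicate 1, lower over all genes tested and 3 lower adjusted over the list alone. Here camera's adjusted p of 0.0316 became 0.0901 without WT control replicate 1, 0.0752 without WT control replicate 3 and 0.0573 without WT compressed replicate 3, and the adjusted p was 0.41 with an estimated correlation. Wnt targets had a median of -0.56 over 12 members. Over all genes tested TCF7 changed by -0.58 ± 0.16 and NOTUM, a secreted Wnt inhibitor, by -1.38 ± 0.38, while 1 member rose. Adjusted over the list alone 5 fell and 1 rose. With camera the adjusted p of 0.0316 became 0.0932 without WT control replicate 3, and the adjusted p was 0.445 with an estimated correlation.

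Junction, nuclear envelope and mechanosensing lists were not called by camera in WT cells, although single members passed the edgeR test. YAP and TEAD targets, which respond to cell shape and density, had a camera adjusted p of 0.0691, with 4 of 25 members lower over all genes tested and 5 lower adjusted over the list alone. ARHGEF17 changed by -0.80 ± 0.18 and CYR61 by -0.85 ± 0.22. Tight junction genes had a camera adjusted p of 0.916, with CLDN16 at 0.82 ± 0.14 and CLDN1 at 0.75 ± 0.16 as the 2 higher members of 29 by either adjustment, and adjusted over the list alone 2 fell. Of mechanosensitive channel and calcium genes the stretch-activated channel PIEZO1 changed by -0.84 ± 0.20 and the channel TRPV4 by -0.86 ± 0.22. The list as a whole, with 1 of 25 higher and 3 lower over all genes tested and 3 higher and 6 lower adjusted over the list alone, had a camera adjusted p of 0.283. Nuclear envelope genes had a camera adjusted p of 0.975, with a median of 0.02, a mean of -0.04 and a downward test direction. Of their 30 members only TMEM201 fell by either adjustment, with a value of -0.95 ± 0.22. SNAI1, a transcription factor of mesenchymal transition, fell by 1.74 ± 0.28, within a list of 12 whose camera adjusted p was 0.466 and in which 1 member rose and 1 fell over all genes tested, and 1 rose and 2 fell adjusted over the list alone.

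**Figure D2:**
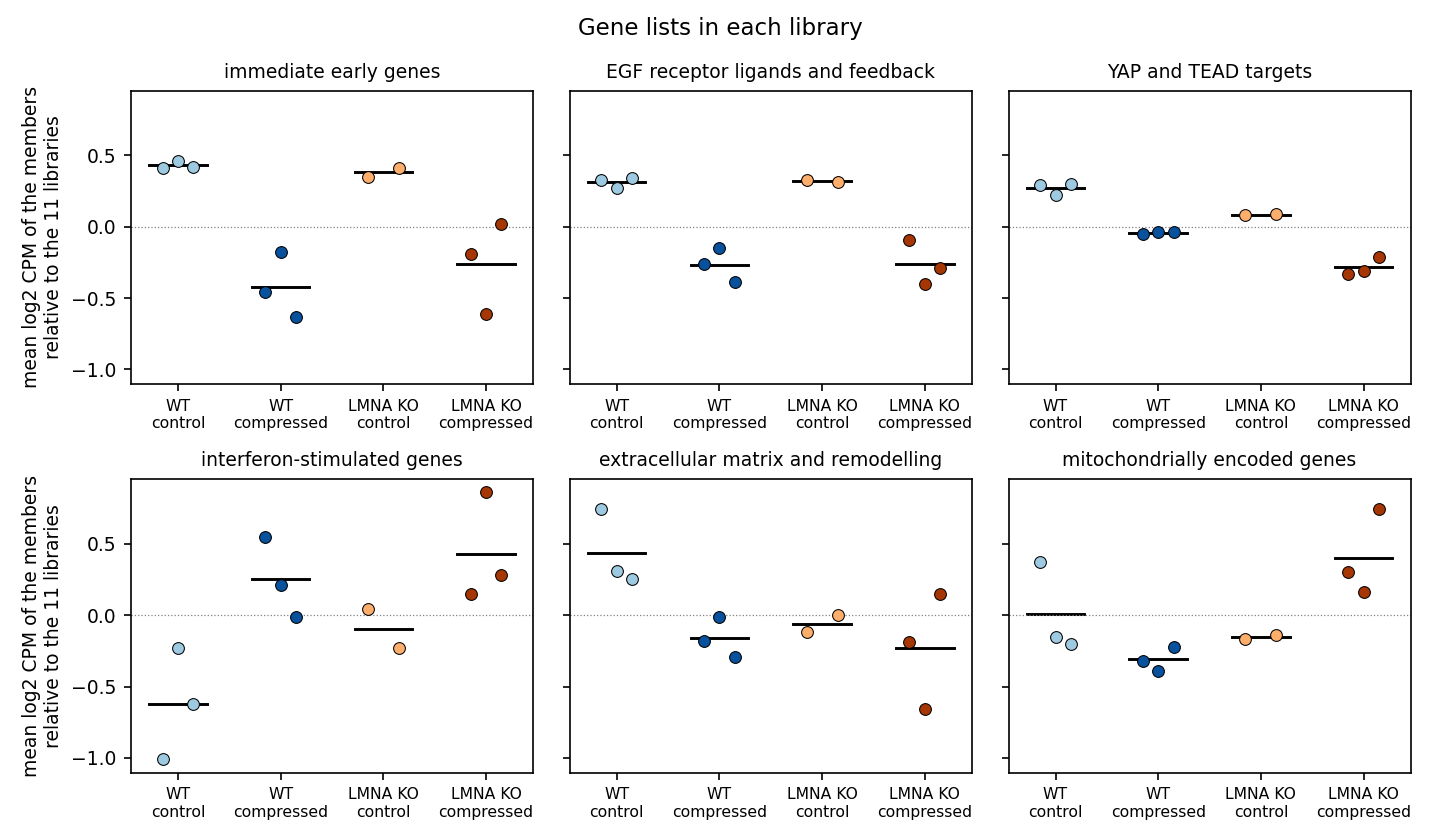
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of the 11 libraries (points), with group means as bars. Immediate early genes score 0.41 to 0.46 in the WT control libraries and -0.63 to -0.18 in the WT compressed libraries.

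In KO cells, immediate early genes, EGF receptor feedback genes and YAP and TEAD targets were lower as groups after compression, and interferon-stimulated, ribosomal protein and mitochondrially encoded genes were higher as groups by limma camera at a preset correlation. The lower groups also passed with an estimated correlation, while the higher ones did not, with camera adjusted p-values of 0.56, 0.687 and 0.324. FOS stood at 92.8 ± 1.91 CPM in KO control cells (SD, n = 2) and at 49.3 ± 3.55 CPM in KO compressed cells (SD, n = 3), and CSRNP1 at 37.4 ± 3.31 and 19.9 ± 3.61 CPM. No single gene passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest adjusted p being 0.306. The test called 0 genes while 828 had an unadjusted p under 0.05, against 678 expected by chance, and DESeq2 called 1 gene, limma on log2(FPKM + 1) called 1 and limma on log2(FPKM + 0.1) called 0. On counts simulated for this comparison edgeR recovered 24% of 200 genes changed by 2-fold and 92.5% of 200 changed by 4-fold, so changes near 2-fold were mostly missed there. Simulated genes varied independently of each other, unlike those of the real libraries, where recovery may differ.

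Camera called 8 of the 33 lists in KO cells, and 3 of them passed with an estimated correlation and by fry, with fry adjusted p-values of 0.0235 for immediate early genes and 0.00354 for EGF receptor feedback and for YAP and TEAD targets. Immediate early genes had a median of -0.58 over 37 members, with a camera adjusted p of 4.61e-11 and 0.0346 with an estimated correlation, and 4 fell adjusted over the list alone against 0 over all genes by edgeR. FOS and CSRNP1 each had a value of -0.91, with SEs of 0.20 and 0.22. EGF receptor ligands and feedback genes had a median of -0.45 over 24 members, with a camera adjusted p of 4.42e-08 and 0.0268 with an estimated correlation. The values of ERRFI1, an inhibitor of the EGF receptor, and of the ligand HBEGF were -1.25 ± 0.37 and -1.05 ± 0.32. YAP and TEAD targets had a median of -0.28 over 25 members, with a camera adjusted p of 0.000317 and 0.0346 with an estimated correlation. AMOTL2 had a value of -0.70 ± 0.19 and AJUBA one of -0.57 ± 0.22. Neither of these lists had a member past the edgeR threshold by either adjustment, that is 0 over all genes tested and 0 adjusted over the list alone. The edgeR adjusted p was 0.773 for each of the 6 genes just named and for each gene named in the next paragraph.

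The other called lists lost their calls with an estimated correlation. Ribosomal protein genes had a median of 0.32 over 63 members and a camera adjusted p of 3.4e-11, and the adjusted p was 0.687 with an estimated correlation; RPL35A had a value of 0.77 ± 0.21 and RPS27 one of 0.69 ± 0.21. Mitochondrially encoded genes had a median of 0.56 over 13 members and a camera adjusted p of 1.47e-10, and the adjusted p was 0.324 with an estimated correlation. Adjusted over the list alone 2 rose, MT-ND4 having a value of 0.85 ± 0.21 and MT-ATP8 one of 0.87 ± 0.27. Interferon-stimulated genes had a median of 0.57 over 34 members and a camera adjusted p of 2.11e-09, and the adjusted p was 0.56 with an estimated correlation. Their mean score changed by 0.52, or 0.31 without KO compressed replicate 2, and that of ribosomal protein genes by 0.26, or 0.12 without KO compressed replicate 1. The smallest p among interferon-stimulated genes was that of B2M, the light chain of class I antigen presentation, at 0.64 ± 0.19. Respiratory chain genes encoded in the nucleus had a median of 0.13 over 57 members, with NDUFA2 at 0.96 ± 0.27 and NDUFB9 at 0.66 ± 0.23. Their camera adjusted p of 4.18e-05 became 0.198 without KO compressed replicate 1, and the adjusted p was 0.723 with an estimated correlation. Wnt targets had a median of -0.31 over 12 members, with MYC at -0.62 ± 0.23 and WNT7A at -0.55 ± 0.26. For Wnt targets camera's adjusted p of 0.0238 became 0.0797 without KO control replicate 1, 0.0873 without KO compressed replicate 1 and 0.114 without KO compressed replicate 2, and the adjusted p was 0.56 with an estimated correlation. Apart from the 2 mitochondrially encoded genes, 0 members of these lists passed edgeR adjusted over the list alone.

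Whether the answer to compression differed between the genotypes was tested as an interaction. Mitochondrially encoded genes were lower after compression in WT cells and higher in KO cells, with a median interaction of 0.98 on the log2 scale over 13 members, all of them positive. The camera calls of this list did not hold with an estimated correlation, the adjusted p being 0.635 in WT cells, 0.324 in KO cells and 0.474 for the interaction, and the WT call also ended without WT control replicate 1 (0.52). MT-CO1 stood at 8500 ± 2170 CPM in WT control and 5100 ± 1070 CPM in WT compressed cells, and at 7060 ± 545 and 10400 ± 2870 CPM in the KO pair (SD, n = 3, 3, 2 and 3). Mitosis genes had a negative interaction by camera, with an adjusted p of 0.591 with an estimated correlation, their median change being 0.37 in WT cells and -0.01 in KO cells, where the mean was 0.02 and the test direction upward. No single gene passed: edgeR called 0 of 13560 genes with a smallest adjusted p of 0.939, 650 genes had an unadjusted p under 0.05 where chance gives 678, and DESeq2 and limma on log2(FPKM + 1) or log2(FPKM + 0.1) also called 0. Without WT control replicate 1 edgeR called 1 gene, and without KO compressed replicate 2 it called 0 with 2272 genes at an unadjusted p under 0.05. On counts simulated for the interaction edgeR recovered 0 of 200 genes changed by 2-fold and 73% of 200 changed by 4-fold.

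Camera called 7 lists for the interaction, 5 positive and 2 negative, and 0 passed with an estimated correlation or by fry, whose smallest adjusted p was 0.572. Mitochondrially encoded genes had a camera adjusted p of 1.29e-16, and the adjusted p was 0.474 with an estimated correlation. Adjusted over the list alone 11 of them were positive, with MT-CO1 at 1.30 ± 0.33 and ND5 at 1.28 ± 0.32. Mitosis genes had a median of -0.35 and a camera adjusted p of 1.33e-05, with HMMR at -1.22 ± 0.44 and CENPE at -1.18 ± 0.42. The adjusted p was 0.591 with an estimated correlation, as it was for each of the 5 lists that follow. The cholesterol list had a median of 0.39 and a camera adjusted p of 3.18e-05, with the fatty acid desaturase FADS2 at 0.93 ± 0.26 and LSS at 0.61 ± 0.27. Matrix genes had a median of 0.35 and a camera adjusted p of 0.00124, with LOXL2 at 1.59 ± 0.49 and TIMP1 at 1.66 ± 0.55, and 0.0665 without KO compressed replicate 3. NF-kB genes had a median of 0.42 and a camera adjusted p of 0.00292, and 0.0507 without KO control replicate 1. Hypoxia and glycolysis genes had a median of 0.24 and a camera adjusted p of 0.00694, with ALDOC at 1.48 ± 0.47 and PFKFB3 at 1.5 ± 0.49. Cilium genes had a median of -0.19 and a camera adjusted p of 0.00812, with IFT88 at -1.12 ± 0.37 and IFT52 at -0.81 ± 0.31, and 0.0686 without KO compressed replicate 1 and 0.138 without KO compressed replicate 3. On mean list scores the interaction of cholesterol genes was 0.29, or 0.18 without WT control replicate 1, and that of matrix genes 0.42, or 0.27 without WT control replicate 1, 0.23 without KO compressed replicate 3 and 0.63 without KO compressed replicate 2. Hypoxia genes had 0.18, or 0.11 without WT compressed replicate 3 and 0.3 without KO compressed replicate 2, and cilium genes -0.23, or -0.15 and -0.37 without KO compressed replicates 1 and 2. The edgeR adjusted p of every gene in this paragraph was 0.939. In the 6 lists other than the mitochondrially encoded one, 0 members passed edgeR adjusted over the list alone.

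Across all 13560 genes the log2 fold changes of compression in the 2 genotypes, which share no library, had a Pearson r of 0.41 and a Spearman rho of 0.53. Genes are not independent replicates, so no p-value is given for these. Of the 522 genes that rose in WT cells 490 had a positive value in KO cells, and of the 326 that fell 285 had a negative value, 91.4% in all. The median ratio of the KO to the WT log2 fold change over these genes was 0.36, where the larger values are those selected in WT cells. The r was 0.28 without KO control replicate 1, 0.16 without KO control replicate 2 and 0.17 without KO compressed replicate 2, and 0.65 over genes with a mean of at least 10 CPM. In both genotypes the fold changes also fell with local gene density, with a Spearman rho of -0.42 in WT and -0.31 in KO cells. How much of the agreement goes with that trend was not tested.

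**Figure D3:**
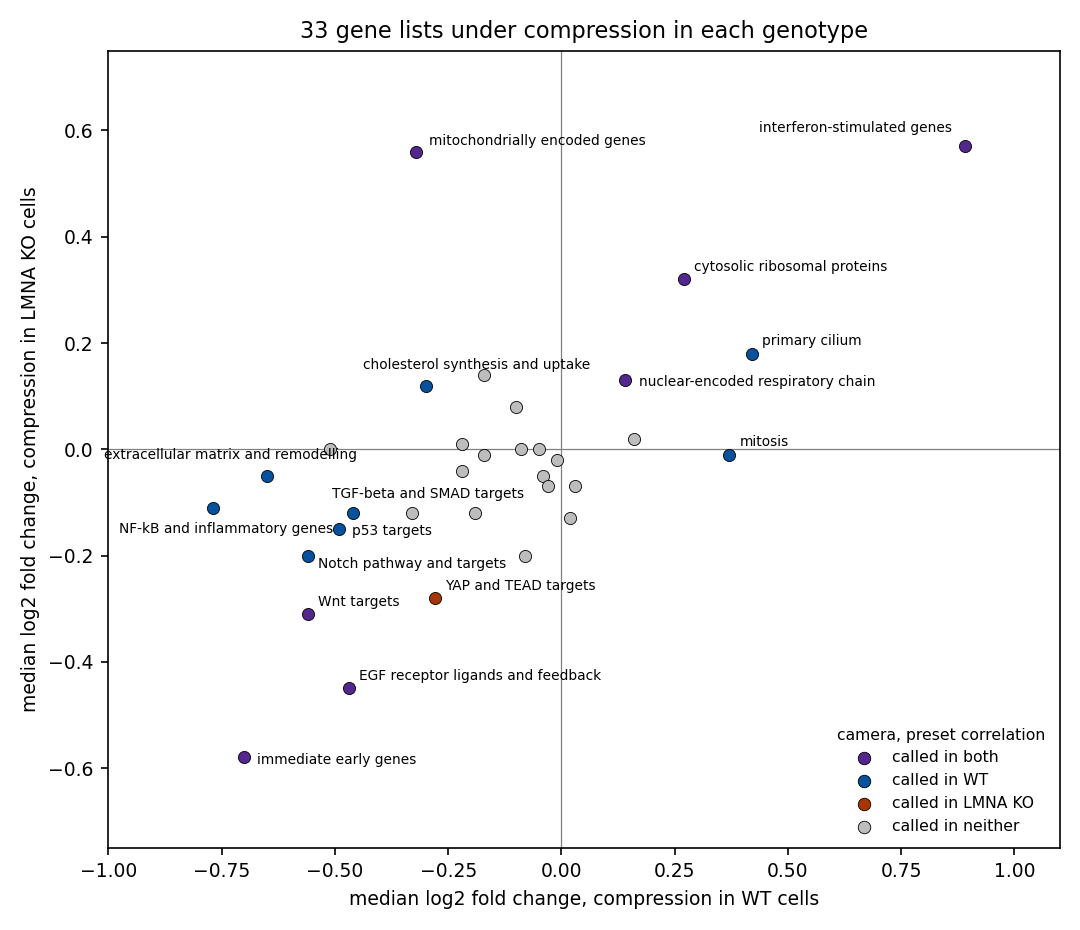
Median log2 fold change of each of 33 gene lists after compression in WT cells (horizontal axis) and in LMNA KO cells (vertical axis), coloured by which genotype camera called the list in. Mitochondrially encoded genes sit at -0.32 in WT and 0.56 in KO cells, and immediate early genes at -0.70 and -0.58.

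Without compression, KO cells held more RNA than WT cells of the retinol-binding protein RBP4 and its receptor STRA6, of the tight junction channel CLDN2 and of the ubiquitin ligase RNF128, and less of the collagen chain COL5A1 and of several transcription factors. RBP4 stood at 21.8 ± 10.7 CPM in WT cells (SD, n = 3) and 90.1 ± 1.94 CPM in KO cells (SD, n = 2), CLDN2 at 6.99 ± 2.22 and 30.8 ± 1.13 CPM, and COL5A1 at 40.1 ± 6.11 and 5.22 ± 0.684 CPM. The transcription factors POU3F3 and GATA4 had 6.87 ± 1.13 and 3.62 ± 0.639 CPM in WT control cells and 0 reads in every KO library. Whether the KO cells are a single clone is not given in the sources used here. An effect of losing LMNA can therefore not be told apart from other differences between the lines, in either treatment or in the interaction. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment 46 of 13560 genes differed, 18 higher and 28 lower in KO cells, with 1056 at an unadjusted p under 0.05. The count was 21 without WT control replicate 2, 16 without WT control replicate 3, 6 without KO control replicate 1 and 8 without KO control replicate 2, and among libraries outside the comparison it was 24 without WT compressed replicate 1 and 106 without KO compressed replicate 2. DESeq2 called 125 genes, and limma on log2(FPKM + 1) called 16.

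The 6 largest increases were STRA6 on chromosome 30 at 3.62 ± 0.56 on the log2 scale (SE), a chromosome 31 locus matched to SON at 2.90 ± 0.50, the uroplakin UPK3B at 2.74 ± 0.30, RNF128 at 2.44 ± 0.22, CLDN2 at 2.13 ± 0.29 and RBP4 at 2.04 ± 0.32. The match to SON is shared by another locus, so which gene it is stays uncertain. RNF128 lies on chromosome X from 80297969 to 80356139 and CLDN2 on the same chromosome from 80456159 to 80489644. Their edgeR adjusted p-values ran from 0.000203 for RNF128 to 0.0239 for the SON locus. Among the largest decreases the KO control libraries held 0 reads of POU3F3, GATA4, GPRASP1 and ARMCX5. Against a floor of 3 counts over the group these were at least 83.8-fold, 44.1-fold, 27.5-fold and 25.0-fold lower, and the floor covers counting error only. FOLH1, a peptidase, had 1 read in KO control cells, a ratio of 197 with a counting interval of 35.0 to 7820. Their edgeR adjusted p-values were 0.000458, 0.00598, 0.0164, 0.019 and 0.0025. Of 16 called genes that the rule for named genes takes in this comparison, LMNA, UPK3B, RNF128 and POU3F3 kept their calls without each library in turn, while KO control replicate 1 ended 12 of the calls and KO control replicate 2 ended 11.

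Camera called 6 lists between the genotypes without compression, and 0 passed with an estimated correlation or by fry, whose smallest adjusted p was 0.271. Interferon-stimulated genes were higher in KO cells with a median of 0.57 over 34 members and a camera adjusted p of 1.06e-06, and the adjusted p was 0.572 with an estimated correlation. Their mean score differed by 0.52, or 0.33 without WT control replicate 1. HERC6 had a value of 0.78 ± 0.20 and IFI44L one of 1.54 ± 0.48, with edgeR adjusted p-values of 0.226 and 0.358. Matrix and remodelling genes were lower with a median of -0.42 over 33 members, COL5A1 at -2.94 ± 0.42 and LOXL2 at -1.99 ± 0.38 being the 2 that fell both over all genes and adjusted over the list alone. The list had a camera adjusted p of 2.6e-05, and the adjusted p was 0.481 with an estimated correlation. Ribosome biogenesis genes were lower with a median of -0.22 over 38 members, 33 of them negative, and DKC1 and NOP14 each had a value of -0.49 ± 0.17 with edgeR adjusted p-values of 0.438 and 0.471. By camera the adjusted p was 2.6e-05, and the adjusted p was 0.481 with an estimated correlation. Cilium genes were higher with a median of 0.25 over 39 members and a camera adjusted p of 0.00155, and the adjusted p was 0.572 with an estimated correlation. PKD2, the polycystin channel, had a value of 0.57 ± 0.21 with an edgeR adjusted p of 0.524. TGF-beta and SMAD targets were lower with a median of -0.25 over 24 members, FSTL1 at -1.22 ± 0.21 being the 1 that fell by either adjustment. Their camera adjusted p of 0.037 became 0.196 without WT control replicate 1, 0.0757 without WT control replicate 2 and 0.0835 without KO control replicate 1, and the adjusted p was 0.481 with an estimated correlation.

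Ribosomal protein genes were also lower without compression, with a median of -0.15 over 63 members. RPS16 had a value of -0.34 ± 0.15 with an edgeR adjusted p of 0.626. Their camera adjusted p of 0.037 became 0.452 without KO control replicate 1, 0.128 without WT control replicate 2 and 0.209 without WT control replicate 3, and the adjusted p was 0.855 with an estimated correlation. Outside the called lists CDH2, the cell adhesion protein N-cadherin, fell by 2.75 ± 0.42 in KO cells, WNT7A by 1.36 ± 0.26, and NQO1, an antioxidant enzyme, rose by 0.74 ± 0.13, with edgeR adjusted p-values of 0.0127, 0.048 and 0.0321. In the interferon, ribosome biogenesis, cilium and ribosomal protein lists 0 members passed edgeR over all genes tested and 0 adjusted over the list alone.

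**Figure D4:**
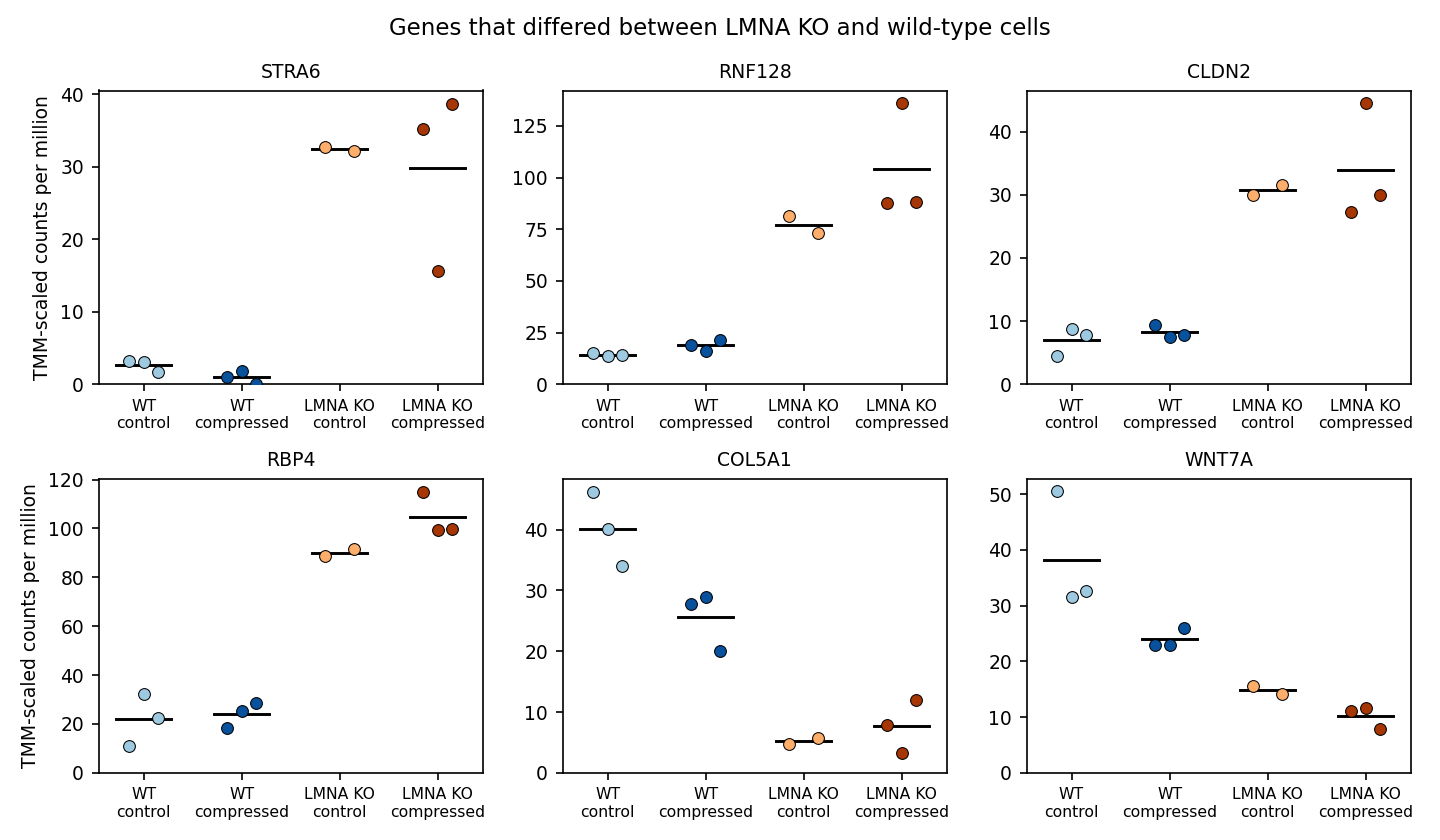
TMM-scaled CPM in each of the 11 libraries (points) for 6 genes called between the genotypes in both treatments, with group means as bars. RNF128, for example, averages 14.3 and 18.8 CPM in WT control and compressed cells and 77.3 and 104 CPM in the KO pair.

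After compression the genotypes differed in many of the same genes, KO cells again holding more RBP4, STRA6, CLDN2 and RNF128 RNA and no reads of POU3F3 or GATA4. The water and glycerol channel AQP3 was higher in KO cells, at 14.8 ± 9.04 CPM against 2.33 ± 0.446 CPM in WT cells (SD, n = 3 each), as was HNF4A, a transcription factor of tubule and liver epithelium, at 23.3 ± 3.65 against 10.5 ± 1.90 CPM. DDX21, a helicase of ribosome assembly, was lower at 134 ± 5.61 against 229 ± 30.0 CPM. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment 107 of 13560 genes differed, 69 higher and 38 lower in KO cells, with 1530 at an unadjusted p under 0.05. The lists of called genes with and without compression shared 16 genes higher in KO cells, where independent lists would share 0.0916, and 22 lower, where they would share 0.0785. The 2 comparisons have no library in common, but one fit of all 11 libraries gave the spread used in both. Both also compare the same 2 lines. The numbers for independent lists are therefore a rough reference, and as genes are not independent no p-value is given for these overlaps. The count of 107 was 46, 39 and 49 without WT compressed replicates 1, 2 and 3, 60, 349 and 50 without KO compressed replicates 1, 2 and 3, and 189 without WT control replicate 1, which lies outside the comparison. DESeq2 called 352 genes, limma on log2(FPKM + 1) called 59 and limma on log2(FPKM + 0.1) called 50.

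The largest increases after compression were STRA6 at 4.90 ± 0.60 on the log2 scale (SE), the SON-matched locus at 3.45 ± 0.51, the lipoxygenase ALOX15B at 3.43 ± 0.67, C10orf54 at 3.25 ± 0.57, the DNA sensor IFI16 at 3.23 ± 0.62 and FAM149A at 3.00 ± 0.64. Their edgeR adjusted p-values were 0.00162, 0.00458, 0.03, 0.0165, 0.0254 and 0.0488. The KO compressed libraries held 0 reads of FOLH1, POU3F3, GATA4, GPRASP1 and ZFP82. Against the floor of 3 counts over the group these were at least 121-fold, 109-fold, 43.5-fold, 40.6-fold and 36.2-fold lower. Their edgeR adjusted p-values lay between 0.0001 for POU3F3 and 0.00585 for ZFP82. Of 18 called genes that the rule takes in this comparison 9 kept their calls without each library in turn, among them LMNA, STRA6, the SON locus and the genes just named with 0 reads. ALOX15B, IFI16, FAM149A, AQP3, HNF4A, DDX21, FADS2 and MT-CO1 each lost the call without any 1 library of the comparison other than KO compressed replicate 2, and C10orf54 lost it without WT compressed replicate 1, WT compressed replicate 2 or KO compressed replicate 3.

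Camera called 9 lists after compression, 4 higher and 5 lower in KO cells, and 0 passed with an estimated correlation, while 4 passed by fry, YAP and TEAD targets (adjusted p of 0.0187) and nuclear envelope, DNA replication and ribosome biogenesis genes (0.0211 each). Mitochondrially encoded genes were higher with a median of 0.72 over 13 members. MT-CO1, at 1.03 ± 0.22, was the 1 member that passed over all genes, and 11 rose adjusted over the list alone. Camera's adjusted p was 3.69e-13, and the adjusted p was 0.198 with an estimated correlation. Ribosome biogenesis genes were lower with a median of -0.35 over 38 members, 37 of them negative. DDX21, at -0.77 ± 0.16, was the 1 that fell over all genes, and 4 fell adjusted over the list alone. Tested with camera, the list had an adjusted p of 5.93e-11, and the adjusted p was 0.198 with an estimated correlation. The cholesterol list was higher with a median of 0.28 over 29 members. The 1 member that rose by either adjustment was FADS2 at 0.96 ± 0.17, a fatty acid desaturase and not an enzyme of cholesterol synthesis. The list had a camera adjusted p of 0.000131, and the adjusted p was 0.658 with an estimated correlation. DNA replication genes were lower with a median of -0.14 over 42 members, and POLA1 had a value of -0.65 ± 0.18 and CDC6 one of -0.49 ± 0.14, with edgeR adjusted p-values of 0.131 and 0.159. The camera adjusted p was 0.000738, and the adjusted p was 0.224 with an estimated correlation. The nuclear envelope list was lower with a camera adjusted p of 0.00314, LMNA itself being the 1 of 30 members that fell by either adjustment, and the adjusted p was 0.198 with an estimated correlation. With LMNA taken out of that list after its value was seen, the camera adjusted p was 0.204 over 29 members. The fry adjusted p of 0.0211 for the nuclear envelope list includes LMNA, the gene knocked out, and no fry value without it is given.

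Mitosis genes were lower in KO compressed cells with a median of -0.18 over 41 members, KIF2C at -0.68 ± 0.22 having an edgeR adjusted p of 0.222. Their camera adjusted p of 0.00425 became 0.401 without KO compressed replicate 3, and the adjusted p was 0.731 with an estimated correlation. Renal transport genes were higher with a median of 0.25 over 31 members. AQP3 at 2.66 ± 0.47 and HNF4A at 1.14 ± 0.24 were the 2 that rose over all genes and 1 fell, while 5 rose and 2 fell adjusted over the list alone. For these genes camera's adjusted p of 0.0331 became 0.291 without WT compressed replicate 3 and 0.241 without KO compressed replicate 3, and the adjusted p was 0.658 with an estimated correlation. YAP and TEAD targets were lower with a median of -0.14 over 25 members. F3, the initiator of clotting, had a value of -0.84 ± 0.18 with an edgeR adjusted p of 0.0507, and 1 member fell adjusted over the list alone against 0 over all genes by edgeR. For YAP and TEAD targets camera's adjusted p of 0.0331 became 0.0539 without WT compressed replicate 2, 0.0877 without KO compressed replicate 1 and 0.104 without KO compressed replicate 3, and the adjusted p was 0.198 with an estimated correlation. Interferon-stimulated genes were higher with a median of 0.25 over 34 members, BST2 at 0.76 ± 0.27 having an edgeR adjusted p of 0.276. For interferon-stimulated genes camera's adjusted p of 0.0331 became 0.116 without WT compressed replicate 2, 0.33 without WT compressed replicate 3 and 0.927, with a downward direction, without KO compressed replicate 2, and the adjusted p was 0.841 with an estimated correlation. In the DNA replication, mitosis and interferon lists 0 members passed edgeR over all genes and 0 adjusted over the list alone.

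Markers of other cell types were mostly at or near 0. Of 18 fibroblast and smooth muscle markers 16 stayed under 1 CPM in every group, as did 13 of 16 endothelial and 17 of 18 immune markers found in the count table. The most abundant were the endothelial receptor FLT1 at 74.78 to 93.5 CPM over the 4 groups, EGFL7 at 20.47 to 41.15 CPM and the smooth muscle myosin MYH11 at 20.04 to 26.82 CPM. COL1A1, DCN, PTPRC and CDH5 were each under 0.13 CPM in every group. None of the 8 markers abundant enough to test passed the edgeR quasi-likelihood test in any of the 4 comparisons of groups.

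The libraries also differed along a trend with local gene density. In WT cells the log2 fold change of compression fell with the number of genes per Mb around each gene, with a Spearman rho of -0.42 across 13399 genes, and the median was 0.25 in the 2882 genes of sparse regions against -0.44 in the 2733 genes of dense regions. In KO cells the rho was -0.31, with medians of 0.13 and -0.18, but it was -0.08 without KO compressed replicate 2 and WT compressed replicate 3, left out together, of which only the first is a KO library. The slope was lowest in WT compressed replicate 3 at -0.206 and KO compressed replicate 2 at -0.249, and those libraries also lay farthest along the first principal component, which held 38.4% of the variance. After a correction of each library for this trend, chosen after it was seen, edgeR called 513 genes for compression in WT cells, 435 of them among the 848. Without WT control replicate 1, WT compressed replicate 3 and KO compressed replicate 2, left out together after their values were seen, edgeR called 3497 genes for compression in WT cells, 13 in KO cells and 362 for the interaction. The share of counts from mitochondrially encoded protein genes was 3.01 ± 0.654% in WT control and 2.09 ± 0.0794% in WT compressed cells, and 2.59 ± 0.0424% and 3.59 ± 0.964% in the KO pair (SD, n = 3, 3, 2 and 3). The change in this share differed between the genotypes by 1.92 percentage points, with an exact permutation p of 0.015 two-sided over 200 arrangements of libraries within each genotype, where 0.005 is the smallest p possible. The test was chosen after the values were seen. It assumes no effect of compression in either genotype, so it does not test equal changes exactly. On the list score of mitochondrially encoded genes its p adjusted over lists was 0.33. The WT change of -0.92 points was -0.54 without WT control replicate 1, and the KO change of 1.0 was 0.46 without KO compressed replicate 3.

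**Figure D5:**
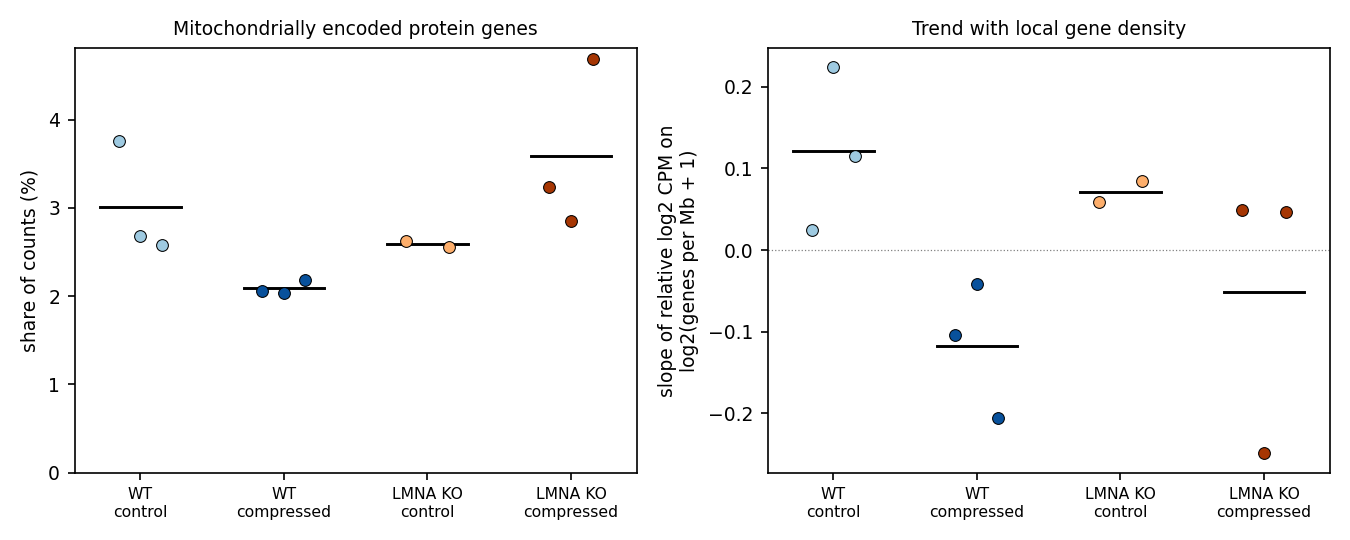
Share of counts from mitochondrially encoded protein genes in percent (left) and slope of relative log2 CPM on log2 local gene density (right) in each library (points), with group means as bars. WT compressed replicate 3 and KO compressed replicate 2 have the lowest slopes, -0.206 and -0.249.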

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

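The tests of explanations and the exact tests of the mitochondrial share and of list scores in this part were chosen only after the results were seen, while the interaction tests of gene lists with limma camera were planned.

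Limma camera at a preset correlation called the response of 7 gene lists to compression different between the genotypes. With a correlation estimated for each list 0 of them passed, the adjusted p being 0.474 for mitochondrially encoded genes and 0.591 for the others, and an exact test on list scores gave adjusted p-values of 0.33 for mitochondrially encoded genes, 0.981 for the primary cilium and 0.939 for the other lists. At the preset correlation the camera adjusted p-values were 1.29e-16 for mitochondrially encoded genes, 1.33e-05 for mitosis, 3.18e-05 for cholesterol synthesis and uptake, 0.00124 for extracellular matrix and remodelling, 0.00292 for NF-kB and inflammatory genes, 0.00694 for hypoxia and glycolysis and 0.00812 for the primary cilium. Leaving out a library ended the calls of matrix genes (0.0665 without KO compressed replicate 3), NF-kB genes (0.0507 without KO control replicate 1) and cilium genes (0.0686 and 0.138 without KO compressed replicates 1 and 3). By edgeR 0 single genes passed for the interaction, with 650 at an unadjusted p under 0.05, and DESeq2 also called 0. The change in the share of counts from mitochondrially encoded protein genes also differed between the genotypes, by 1.92 percentage points, with an exact p of 0.015 over 200 arrangements. The exact tests of list scores and of this share assume no effect of compression in either genotype. They are therefore not exact tests of equal responses.

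Mitochondrially encoded RNAs were lower after compression in wild-type cells and higher in LMNA KO cells by camera at the preset correlation, with adjusted p-values of 0.635 and 0.324 with an estimated one, and the wild-type call ended without WT control replicate 1 (0.52). A single library with a high share in each genotype carried much of the size. The change went from -0.92 to -0.54 points without WT control replicate 1 and from 1.0 to 0.46 without KO compressed replicate 3, with the direction kept. The control and compressed libraries did not overlap, with gaps of 0.23 percentage points in KO cells and 0.4 in wild-type cells. Both of these libraries hold the highest share of their group, so leaving them out could not change the gaps, which decide nothing about them. Sequencing depth is argued against by group means only. The mean total of the compressed libraries was 0.788 of the control mean in KO cells and 0.815 in wild-type cells, while the share moved in opposite directions. The wild-type groups overlapped in depth, with 13039463 counts in WT compressed replicate 1 and 12715099 in WT control replicate 1. The trend with gene density stays open, because these genes have no density value and a correction that left an adjusted p of 9.23e-20 could not move them. RNA quality and the yield of oligo(dT) capture were not tested and stay open, as does a difference between the genotypes, for which the exact test on the list score is given above.

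Genes were called for compression in wild-type cells, 848 by edgeR, and 0 in LMNA KO cells, where 828 had an unadjusted p under 0.05 and DESeq2 called 1. The KO group has 1 control library fewer, which raises the variance of the contrast by a factor of 1.25, and with that error the wild-type effects gave 0 calls by edgeR. Wild-type fits with 1 control library fewer called 1379, 1 and 1 genes without replicates 1, 2 and 3, which does not decide whether this accounts for the missing calls, since all calls lay near the threshold. At an unadjusted p under 0.05 these fits gave 4827, 2909 and 3236 genes, against 828 in KO cells and at most 1636 with 1 KO library left out, which argues against library number as the whole source of that gap. A response that differs between the genotypes stays open: the interaction had 650 genes with a p under 0.05 where chance gives 678, but 2272 without KO compressed replicate 2, and 3187 with 362 called without 3 libraries chosen after their values were seen.

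Compression log2 fold changes fell with local gene density. Over rearrangements of libraries within each genotype the slope, averaged over both genotypes, had an exact p of 0.025. Differences between libraries that do not follow compression stay open, because 1 library made most of the KO part. In KO cells the compressed slopes were 0.049, -0.249 and 0.046, against 0.059 and 0.084 in the controls. In wild-type cells they were -0.104, -0.042 and -0.206, below the controls at 0.024, 0.224 and 0.115. After every library was thinned to the lowest total the exact p was again 0.025. Thinning keeps the expected CPM, so this could not show what sequencing depth does, and depth stays open. Without the 2 compressed libraries that stand apart the Spearman rho was -0.4 in wild-type cells, which argues against them as the source there, and -0.08 in KO cells, where KO compressed replicate 2 may account for the trend. GC content goes with gene density and was not analysed here, so a bias of library preparation with GC stays open.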

How the results depend on the processing

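The fits without 3 or 2 libraries and the correction for local gene density were chosen only after the results were seen, as were the tests on other splits of the libraries.

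Counts by edgeR stayed within 1.5 times those of the report under RLE scaling, library size alone, a stricter filter and a robust fit for all 5 gene comparisons. The other settings moved counts as follows, and the cause was not tested unless given. DESeq2 called 2476 genes for compression in wild-type cells, 1 in LMNA KO cells, 125 between the genotypes without compression and 352 after it. With no filter on low counts the numbers were 1754, 90 and 201 for wild-type compression and the genotypes without and after compression. Limma on log2(FPKM + 1) called 0 for wild-type compression (4160 at an unadjusted p under 0.05), 1 in KO cells, 16 and 59 between the genotypes, and on log2(FPKM + 0.1) it called 1, 8 and 50 for wild-type compression and the genotypes. A fit of the 2 groups alone called 2069 for wild-type compression and 64 between compressed genotypes. Of the 848 genes, 307 changed by at least 1 on the log2 scale. The density correction gave 513.

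Without WT control replicate 1, WT compressed replicate 3 and KO compressed replicate 2 the counts were 3497 for wild-type compression (827 of the 848 among them), 13 in KO cells, 802 and 723 between the genotypes and 362 for the interaction, and 9 lists were called in wild-type cells. Without the last 2 of these libraries 111 genes differed between the genotypes without compression. A term for the replicate number gave 0 genes by edgeR for wild-type compression (3439 at an unadjusted p under 0.05), 15 and 53 between the genotypes. No pairing by replicate number was seen, since of 15 pairs with the same number only 1 had a correlation over 0.1, the range being -0.35 to 0.2 against -0.25 to 0.37 in other pairs. With so few libraries per group these correlations cannot exclude a pairing.

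With a correlation estimated per list the counts of lists were 0 for wild-type compression, 3 in KO cells, 0 and 0 between the genotypes and 0 for the interaction, since camera then allows for members moving together. The correlation of the responses in the 2 genotypes was 0.65 over genes with a mean of at least 10 CPM.

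Leaving out each library of the groups compared in turn gave 0 to 1379 genes for wild-type compression, 0 in KO cells each time (edgeR, 203 to 1636 at an unadjusted p under 0.05), 6 to 43 and 39 to 349 between the genotypes without and after compression, and 0 to 1 for the interaction. Lists ranged from 8 to 18, 8 to 10, 7 to 10, 8 to 11 and 6 to 10 in the same order, and the correlation of responses from 0.16 to 0.49. Libraries outside a comparison also moved its count, and the cause was not tested, wild-type compression reaching 3066 without KO compressed replicate 2 and 0 by edgeR without either KO control (3897 and 3899 at an unadjusted p under 0.05), and the genotypes without compression reaching 106 without KO compressed replicate 2 and 24 without WT compressed replicate 1.

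Of 130 results for named genes, 645 values under other settings were on the same side of the threshold in 514 cases, weaker in 125 and stronger in 6. With a library left out, 814 values were the same in 489 cases, weaker in 322 and stronger in 3. In neither set did a result that was called in the main fit change direction. A change of direction in a result not called there was counted as the same, so such changes are not excluded.

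For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In wild-type cells 1 of the 10 splits gave as many genes, the real one with 848 against 0 at most elsewhere, and 2 gave as many lists, 15 against up to 16. Between compressed genotypes 1 split gave as many genes, 107 against 0, and 3 gave as many lists, 9 against up to 10. Whether the lists called in other splits come from a structure of the samples or from the preset correlation was not tested.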

Other observations

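All tests in this part were chosen only after the results were seen.

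A single fit of the average compression effect over both genotypes called 756 genes by edgeR, 452 higher and 304 lower, of which 457 were among the 848 called in wild-type cells. The count was 2106 without WT control replicate 1, 7 without WT control replicate 2, 3 without WT compressed replicate 3, 1888 without KO compressed replicate 3 and 447 without KO compressed replicate 2. It was 0 without WT control replicate 3, WT compressed replicate 1, KO control replicate 1 or KO control replicate 2.

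One hypothesis was that the genotypes share a response to compression, read from list scores per library. The mean change over both genotypes was -0.58 for EGF receptor ligands and feedback, -0.34 for YAP and TEAD targets and -0.32 for p53 targets, each with an exact p of 0.005, the smallest that 200 arrangements can give. Adjusted over lists the smallest exact p was 0.055, which did not pass the threshold. The test takes the average over both genotypes, which a change in a single genotype can also move, so it cannot decide whether the response is shared. In WT and KO cells the changes were -0.58 and -0.58 for EGF receptor ligands and feedback. They were -0.32 and -0.37 for YAP and TEAD targets, and -0.42 and -0.22 for p53 targets.

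Genes that differ between the genotypes could cluster where the 2 lines differ by region. Among 115 genes called in either comparison there were 13 pairs of neighbours within 1 Mb, 9 of them in the same direction, against a median of 10 in 10000 draws of tested genes and an upper 95th percentile of 16 (one-sided permutation p of 0.23), which does not decide it. The pairs include RNF128 and CLDN2, 146 kb apart on chromosome X, and ARMCX5 and GPRASP1, 42 kb apart on the same chromosome.

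A change that extends to the genes around LMNA was tested beside the loss of LMNA RNA in the KO cells. Of 58 tested neighbours within 1 Mb, 0 were called by edgeR in either comparison of the genotypes, and their median log2 fold changes were -0.09 without compression and -0.01 after it. Chance alone would call 0.488 of them, so the count does not decide it. Whether the KO cells are one clone is not given in the sources used here.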
